A study of Homo sapiens with 3 samples.

How the data were processed

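Total RNA of GM0637 fibroblasts was taken at 0 h, 4 h and 8 h of neocarzinostatin treatment. Per the labels' protocols, rRNA was removed, the RNA was amplified and transcribed into Cy3-labelled cRNA by random priming, and each sample was hybridized to an Agilent array in 1 colour. Groups were taken from the labels and hold 1 array each. The labels do not say how many cultures were pooled.

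The deposited scanner files hold the intensity of each spot, made with Agilent Feature Extraction 10.7.3.1 per the file headers, which name build hg19. The software subtracted the background and, on the 0 h and 8 h arrays, also divided by a spatial trend, whose size was 0.0637 and 0.0394 (root mean square of the fit). On the 4 h array no such trend was divided out. The processed intensity is given with 3 significant digits on the 0 h and 8 h arrays and with up to 7 on the 4 h array, per the deposited values. All 3 arrays share 1 scan image, so slide and scan do not differ between the groups. The values are not normalized between arrays.

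The authors' value table gives log2 values for 10584 of the probes, with the normalization not given in the sources used here. Its column medians are 6.63 at 0 h, 6.67 at 4 h and 6.61 at 8 h. Set against log2 of the same array's processed signal, its columns have Pearson correlations of 0.994, 0.997 and 0.997, so the scale is log2 of the signal. The way in which the columns were centred and brought to nearly the same distribution stays unknown. The differences between times in the table and those computed here had correlations across probes of 0.996 (4 h minus 0 h), 0.970 (8 h minus 0 h) and 0.978 (8 h minus 4 h). The table lists 0 of the probes for HOX exons, HOX introns and reference genes.

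Each array has 62738 spots. Spots of control type (1319 per array) and 600 spots of probes named as negative controls were left out, which leaves 60819 spots of 60639 probes. Spots that the software had marked as non-uniform or as population outliers were left out: 3751 at 0 h, 4001 at 4 h and 2869 at 8 h. Such marks fell on 24.0%, 23.8% and 17.7% of the spots well above background and on 0% of the others. Saturated spots were kept for counts (92, 59 and 20 spots), and a gene saturated on either array of a comparison was given only a bound. Spots of 1 probe were averaged. A probe counted as detected where the software marked its signal as well above background.

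Since under 50% of the probes were detected, the main measure was log2 of the processed signal minus each array's 75th percentile over the 8824 probes detected on all 3 arrays. These percentiles were signals of 853 (0 h), 683 (4 h) and 935 (8 h). The local background averaged 30.7, 30.7 and 36.8, and the lowest signal well above background was 54.1, 42.5 and 73.3, which sets the limit for dim transcripts. Over the spots of a reference-gene probe on 1 array, the median SD was 0.08 on the log2 scale (35 values from 0.03 to 0.27). From this SD, 0.12 was taken as the spread of a single difference. It holds spot noise within an array only and leaves out variation between arrays and cultures.

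With 1 array per time there is no test. Counts are of probes 2-fold or more apart among those detected on both arrays. For a probe detected on 1 array of a pair, the bound is its normalized signal over the higher of its own signal and the lowest signal well above background on the other array. A list's median difference was placed among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. The overlap was simulated from the 8 h minus 4 h differences, resampled within signal bins with random sign and scaled to 1 array, 100 times. On simulated arrays, run for 8 h minus 0 h on 8824 probes, the noise of a difference had an SD of 0.2. There, 50 of 50 probes changed 4-fold and 47 of 50 changed 2.5-fold were counted, 1 of 50 changed 1.5-fold, and 0 of 8624 unchanged probes. The measured differences, which hold any real change too, had SDs of 0.54 to 0.99 over eighths of the probes by signal. The 0 therefore does not give the rate of false counts on the real arrays. For the same comparison, lists of 21 among 9651 probes fell below percentile 2.5 in 4 of 200 unshifted draws and in 163 of 200 draws lowered by 0.5.

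Named genes were chosen by a rule fixed before the data were examined. For each treated time, and separately for noncoding and coding probes, it took up to 6 each way with the largest difference, among probes detected on both arrays, unsaturated, at or above the median signal of detected probes, and 2-fold or more changed the same way after normexp. It added up to 6 each way that changed 2-fold or more at both times, the 3 largest bounds each way, the 4 members with the largest change in each described list, and, wherever measured, 9 fixed damage-response genes with ACTB and GAPDH. A gene with several probes was taken at the brightest of those measured on both arrays. Of 65 RefSeq accessions named in the files, 63 matched a symbol in a RefSeq gene table for GRCh38.p14, used for names only. The names of ultraconserved and noncoding probes are those of the files.

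Alternatives fixed before the data were examined were normexp background correction (offset 50) on the median signal and median background, quantile normalization, median centring, the percentile over all probes, cyclic loess, the authors' value table, bright probes only, no filter on detection, marked spots kept, a 3-fold threshold, a difference beyond 1.96 scanner errors (no test of the counts, since 1.96 errors were under 2-fold for each counted probe), and the mean over probes of a gene. Normexp had been planned on the mean signal, which was not used here. Chosen after seeing the data were the background-subtracted signal before detrending, and counts within the probes of the authors' table. A planned comparison of antisense RNAs with their host genes was left out, because no named pair was found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.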

Results

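GM0637 is a human fibroblast line transformed with SV40. The titles, source and cell line fields of the labels name GM0637, while their description field speaks of MCFs, a term the labels do not explain, and GM0637 is used here. The cells were left untreated (0 h) or were exposed to neocarzinostatin, a drug that mimics ionizing radiation and makes DNA double-strand breaks, and were harvested after 4 h and 8 h. RNA from each time was hybridized in 1 colour to a long-noncoding-RNA array, with 1 array per time and no replicate. The question, per the labels, was how long noncoding RNAs are regulated after DNA damage. Of 60639 target probes, 11738 (19.4%) were well above background and free of outlier flags at 0 h, 12678 (20.9%) at 4 h and 13204 (21.8%) at 8 h, and 8824 on all 3 arrays. Only 1366 probes carry a name in the files. These comprise 962 probes for the plus or minus strand of ultraconserved regions (genome segments identical between human and rodents, written uc. with a number and a strand), 212 probes for noncoding regions of the HOX clusters (nc-HOX), 93 HOX exon probes, 53 HOX intron probes, 20 reference genes and 26 other noncoding probes. The files do not pair the remaining probes with genes. Among named probes, 86 of the 962 ultraconserved, 55 of the 212 nc-HOX and 38 of the 93 HOX exon probes were well above background on at least 1 array.

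All differences are between single arrays, so no test across replicates was possible, and a change means a difference of 2-fold or more between 2 arrays. Beside the log2 difference of a named probe, the ± value is the combined error that the scanner software gives for both spots. It was 0.20 to 0.43 for probes with 1 spot and covers measurement error only. The 3 arrays limit the precision of every statement, since differences between cultures enter it unseen. No untreated array was made at 4 h or 8 h, so effects of time in culture cannot be told apart from those of the drug.

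After 4 h of neocarzinostatin, the named probes with the largest increases came from ultraconserved regions. Signal of uc.50- was 4.21-fold higher than in untreated cells (log2 difference 2.07 ± 0.22), and that of uc.110- was 3.68-fold higher (1.88 ± 0.21). The dimmer uc.109+ was 4.46-fold higher (2.16 ± 0.29), but its difference was 1.24 after normexp background correction. In the other direction, uc.188- was 4.64-fold lower (-2.22 ± 0.20) and uc.403+ 3.42-fold lower (-1.77 ± 0.28). The few named coding genes are only HOX genes and reference genes, and among these the HOX genes had the largest changes. HOX genes encode homeobox transcription factors that mark position along the body axis. HOXD4 was 2.44-fold lower (-1.29 ± 0.20), HOXC11 2.2-fold lower (-1.14 ± 0.21) and HOXA5 2.41-fold higher (1.27 ± 0.21), while HOXB13 differed by less than 2-fold (0.83 ± 0.21). After normexp background correction the difference of HOXA5 was 0.95, under 2-fold.

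In all, 9788 probes were measured on both the 0 h and 4 h arrays, of which 737 (7.53%) were higher and 558 (5.70%) lower at 4 h. A difference under 1.5-fold was found for 6633 probes (67.8%). Another 2361 probes were well above background at 4 h only and 1201 at 0 h only, and for these a bound can be given. The largest bounds among named probes upward were at least 2.65-fold for uc.350+, 2.47-fold for uc.186- and 1.82-fold for nc-HOXC11-108. Downward they were at least 6.24-fold for nc-HOXA4-64, 5.63-fold for uc.90+ and 5.28-fold for the HOXB9 exon 1 probe. With arrays scaled on all probes instead of those detected on all arrays, the split turned to 581 higher and 731 lower.

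After 8 h, the same ultraconserved probes had the largest increases and decreases among bright named noncoding probes. Signal of uc.110- was 5.06-fold higher than at 0 h (2.34 ± 0.21) and that of uc.50- 4.94-fold higher (2.30 ± 0.22), while uc.188- was 6.50-fold lower (-2.70 ± 0.20). The nc-HOXB6-181 probe was 3.35-fold higher (1.75 ± 0.21). CARIntergenic10, named for an intergenic chromatin-associated RNA, was 2.61-fold lower (-1.38 ± 0.22). Lower signal was also found for nc-HOXD1-46 (2.41-fold, -1.27 ± 0.22) and uc.472- (2.30-fold, -1.20 ± 0.21). Among coding genes, HOXD8 was 3.87-fold lower (-1.95 ± 0.22), HOXD4 3.64-fold lower (-1.86 ± 0.21), HOXC11 3.42-fold lower (-1.78 ± 0.21), HOXD3 2.51-fold lower (-1.33 ± 0.21) and HOXB5 2.11-fold lower (-1.08 ± 0.20). The exon 2 probe of HOXB9 was 2.19-fold higher (1.13 ± 0.20). The dimmer HOXB9 exon 1 probe went the other way, being well above background at 0 h only, at least 4.19-fold lower at 8 h. Under 2-fold were HOXB5 after cyclic loess (-0.88) and HOXB9 exon 2 with scaling on all probes (0.71).

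Of 9651 probes measured on both the 0 h and 8 h arrays, 1218 (12.6%) were higher and 729 (7.55%) lower at 8 h, and 5492 (56.9%) differed by less than 1.5-fold. Another 2433 probes were well above background at 8 h only and 1829 at 0 h only. Among named probes, the largest bound upward was that of uc.49+, at least 73.9-fold higher, with a signal of 4380 at 8 h against 12 at 0 h. It was followed by uc.171-, at least 19.6-fold higher, and a probe known in the files only by an Ensembl transcript identifier, at least 7.70-fold higher. Downward, the bounds were at least 4.95-fold for nc-HOXA4-64 and 4.47-fold for uc.90+. Their bounds at 4 h rest on the same 0 h signals (331 and 299), so the 4 h and 8 h bounds are not independent. The split between higher and lower probes turned on the scaling: it was 943 to 1084 after quantile normalization, 1046 to 966 with median centring, 652 to 1918 with scaling on all probes and 336 to 440 in the authors' value table. These choices moved the median difference of the 9651 probes by -0.18, -0.12 and -0.42 on the log2 scale for the first 3, and by -0.20 over the 3705 of them in the table.

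**Figure D1:**
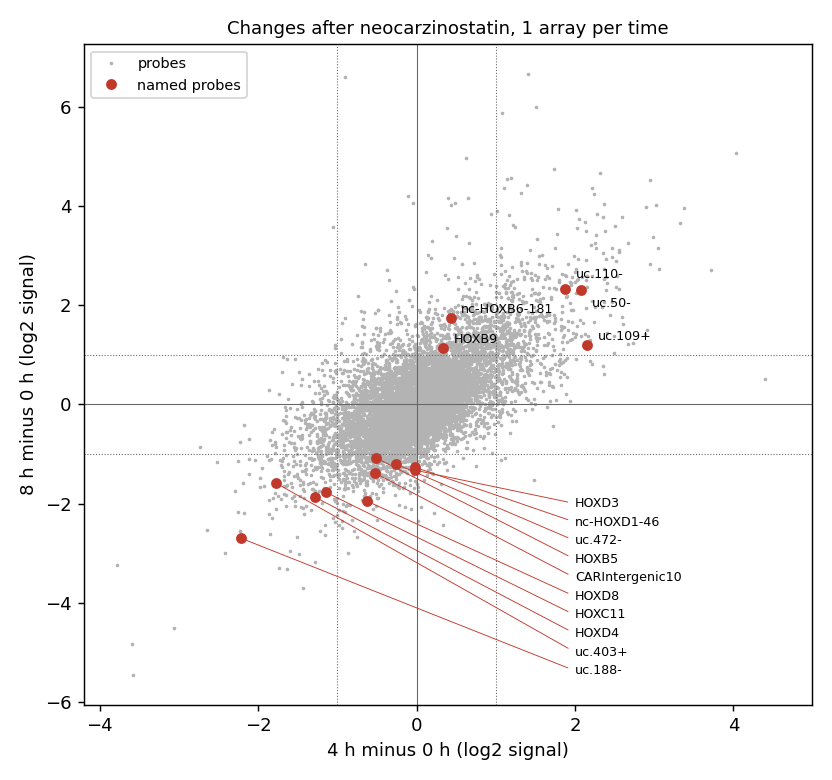
Log2 difference from the untreated array at 4 h (horizontal axis) and at 8 h (vertical axis) for the 8824 probes well above background on all 3 arrays (grey points), with the named probes in red and dotted lines at 2-fold. Of the red points, uc.50-, uc.110- and uc.109+ lie beyond 2-fold upward at both times, and uc.188-, uc.403+, HOXD4 and HOXC11 beyond 2-fold downward at both times.

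Between 4 h and 8 h, signal differed 2-fold or more at several HOX loci. From 4 h to 8 h, HOXD8 was 2.51-fold lower (-1.33 ± 0.22) and HOXD3 2.48-fold lower (-1.31 ± 0.21), although HOXD3 had differed by only -0.02 ± 0.20 at 4 h from the untreated cells. Over the same interval nc-HOXB6-181 was 2.49-fold higher (1.32 ± 0.21) and nc-HOXD1-46 2.36-fold lower (-1.24 ± 0.23). After normexp, HOXD3 was at -0.93 and nc-HOXD1-46 at -0.69, under 2-fold. By contrast, uc.50- and uc.110- differed by 0.23 ± 0.20 and 0.46 ± 0.20. Among 10496 probes measured on both arrays, 1114 were higher and 403 lower at 8 h than at 4 h. This split was 785 to 678 after quantile normalization, 567 to 1016 with scaling on all probes and 271 to 335 in the authors' value table. The lowest normalized log2 signal of a detected probe was -3.67 at 8 h and -4.01 at 4 h, so dim probes that fell could be left out. In the dimmest eighth of the measured probes, 137 were higher and 0 lower.

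Changes at 4 h and 8 h overlapped. Of the 8824 probes detected on all arrays, 463 were higher and 193 lower at both times, and 6 had moved 2-fold or more in opposite ways. With scaling on all probes this split turned to 287 higher and 391 lower. Under the main scaling, 66.7% of the 694 probes higher at 4 h were also 2-fold or more higher at 8 h. Of the 465 lower at 4 h, 41.5% were also lower at 8 h. In reverse, 40.7% of the 1138 probes higher at 8 h and 28.5% of the 677 lower at 8 h were changed the same way at 4 h. Both comparisons use the same untreated array, so a simulation of 3 unchanged arrays already gave 178.03 higher and 176.17 lower at both times, on average over 100 draws. Its noise was taken from the 8 h minus 4 h differences, which hold any real change between these times. The simulated overlap, and the covariance given below, may therefore be too high. Independent lists of these sizes would share 89.5 and 35.7 probes. Across the 8824 probes, which are not independent replicates, the 4 h and 8 h differences had a Pearson correlation of 0.65, against 0.50 in the simulation. Their covariance was 0.39 against 0.24, a difference of 0.15. The simulation gives each array noise of the same size, which fixes its correlation near 0.50 whatever that size. An untreated array with more noise than the others could also give a higher correlation, so 0.65 against 0.50 does not separate it from a shared response. The untreated array could not be split, so the share of the overlap that it brings stays unmeasured. Named members of the overlap, under the main scaling, were uc.50-, uc.110- and uc.109+ upward and uc.188-, uc.403+, HOXD4 and HOXC11 downward. The 8 h difference of uc.109+ was under 2-fold after normexp (0.55), after quantile normalization (0.85), in the authors' value table (0.85) and with scaling on all probes (0.77). Of probes without a gene name, ASHG19A3A035599 was 16.4-fold higher at 4 h and 33.5-fold at 8 h, and ASHG19A3A026604 10.4-fold and 15.6-fold. ASHG19A3A019352 was 11.9-fold lower at 4 h and 43.8-fold at 8 h, and ASHG19A3A039512 12.1-fold and 28.5-fold.

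The HOX coding genes were the only list fixed before the data were examined that had 5 or more members measured, and at 8 h they lay below the other probes of similar brightness. At 4 h, 1 of the 18 measured HOX genes was higher, 2 were lower and 15 did not change 2-fold, with a median log2 difference of -0.06. That median lay at percentile 26.4 of 10000 random lists of probes matched on signal. At 8 h, 8 of 21 were lower, 1 was higher and 12 did not change 2-fold, with a median of -0.43 at percentile 1.65, below the random lists' central 95% of -0.39 to 0.34. Besides HOXD8, HOXD4, HOXC11, HOXD3 and HOXB5, the 8 lower genes included HOXB8 (2.89-fold, -1.53 ± 0.33). The other members, named after their values were seen, were HOXA11 (2.27-fold, -1.18 ± 0.32) and HOXC10 (2.22-fold, -1.15 ± 0.20). From 4 h to 8 h the median difference of 18 HOX genes was -0.57, at percentile 0.01. After normexp the dim HOXB8 was at -0.32 and HOXA11 at -0.23, the bright HOXC10 was at -0.96, and 5 of the 21 genes were 2-fold or more lower. The HOX median at 8 h was below 0 under every scaling tried, and without a filter on detection it was -0.07. HOXD8 is given by its exon 1 probe, since the brighter exon 2 probe carried outlier flags at 0 h and 4 h. Such flags removed 10, 14 and 3 of the 93 HOX exon probes at 0 h, 4 h and 8 h. Bright probes of HOXA9, HOXB4 and HOXD9 were among those lost at 0 h, so the 21 genes leave these out. With marked spots kept the HOX median at 8 h was -0.39, and its percentile was not computed. HOXC6 was measured by 2 probes, which differed at 8 h (-0.63 and 0.97).

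**Figure D2:**
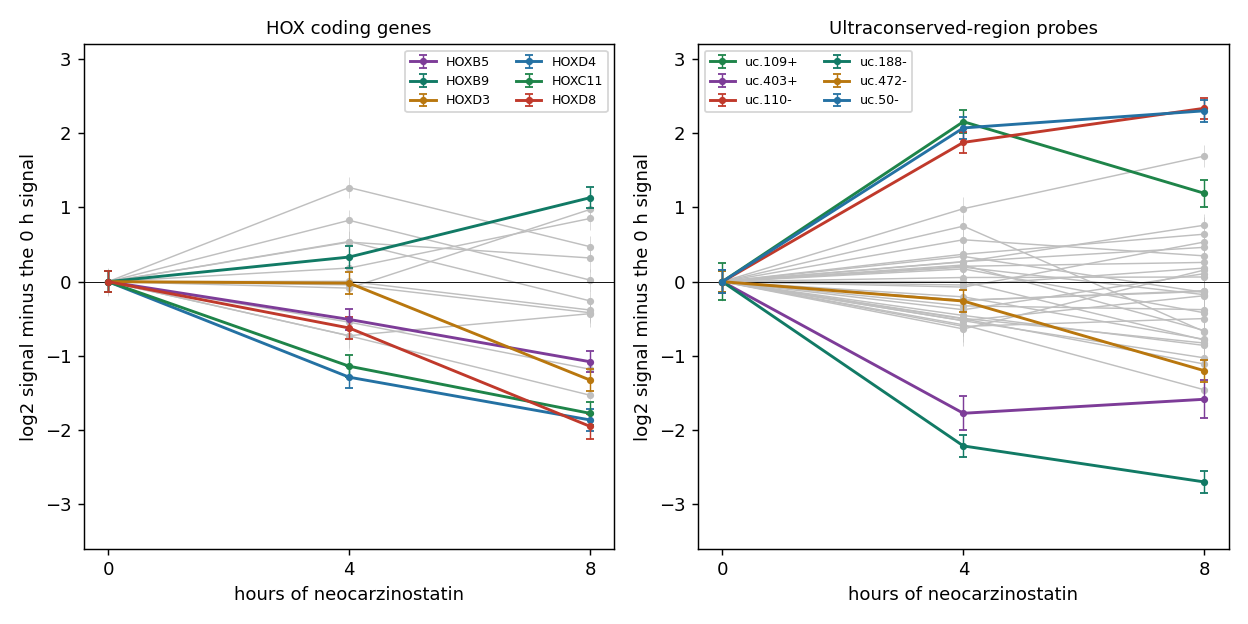
Log2 signal at 0, 4 and 8 h of neocarzinostatin, as the difference from the 0 h signal, for 17 HOX coding genes (left) and 34 ultraconserved-region probes (right) well above background on all 3 arrays, where each line is 1 probe and bars are the scanner software's error of each signal. HOXD8 lies at -1.95 and HOXD4 at -1.86 at 8 h, while uc.110- and uc.50- lie at 2.34 and 2.30.

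Few noncoding probes of the HOX clusters changed. At 8 h, 2 of 37 measured nc-HOX probes were higher and 3 lower, with a median of -0.11 at percentile 19.9 of the matched random lists. That median was -0.38 after quantile normalization (percentile 7.06), -0.38 in the authors' value table, -0.53 with scaling on all probes and 0.21 without a filter on detection, so its direction depends on the filter. These few probes are named after their values were seen: upward nc-HOXB6-181 and nc-HOXB1-156 (2.27-fold, 1.18 ± 0.22), and downward nc-HOXD8-20 (3.02-fold, -1.59 ± 0.26), nc-HOXD4-22 (2.69-fold, -1.43 ± 0.26) and nc-HOXD1-46. All 3 that were lower are in the HOXD cluster, where 10 probes were measured, and the 2 that were higher are in the HOXB cluster, where 14 were. After normexp nc-HOXD4-22 was at -0.98 and nc-HOXB1-156 at 0.88, under 2-fold, which leaves 3 of these 5 changes. HOTAIRM1, a long noncoding RNA of the HOXA cluster, differed by 0.03 ± 0.20 at 8 h and carried an outlier flag at 4 h, when the marked spot differed by -0.08.

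Among ultraconserved regions, 3 of 44 measured probes were higher and 3 lower at 4 h, and 4 of 35 were higher and 6 lower at 8 h. The medians of -0.09 and -0.18 lay at percentiles 21 and 14.3 of the matched random lists. With scaling on all probes they were -0.21 and -0.60, and without a filter on detection the 8 h median was 0.29. Over all named noncoding probes, 5.88% of 85 were higher and 3.53% lower at 4 h, and 7.79% of 77 were higher and 13.0% lower at 8 h. A probe that the files name p53mRNA stands among these 77 (0.19 ± 0.20 at 8 h), although its name is that of a messenger RNA. Over the HOX exon and reference gene probes, the named coding class, 3.45% of 29 were higher and 10.3% lower at 4 h, and 3.03% of 33 were higher and 24.2% lower at 8 h. The median differences at 8 h were -0.14 for noncoding and -0.43 for coding probes, at percentiles 7.41 and 1.98. After cyclic loess the coding median was -0.16 at percentile 6.34, no longer among the lowest 2.5% of random lists. All 8 coding probes that were 2-fold or more lower at 8 h were HOX exon probes, against 0 of 10 reference genes. The lower share of this class thus restates the HOX result and does not describe coding RNAs in general. The difference between both classes was not tested.

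None of the 10 reference genes measured without saturation changed 2-fold at 8 h, yet all 10 lay below the untreated array. Their median log2 difference was -0.44, with the ribosomal protein gene RPS18 at -0.55 and the histone gene H3-3A at -0.45. Probes of similar brightness behaved alike, since random matched lists had medians between -0.66 and -0.04 and the reference genes lay at percentile 33.7. The brightest eighth of all probes had a median of -0.25 and the dimmest of 0.19 at 8 h. After quantile normalization the median of these genes was 0.01 after cyclic loess -0.04 and with scaling on all probes -0.86, so their direction depends on the scaling. At 4 h the median of 9 reference genes was 0.07. The spots of ACTB and GAPDH were saturated at 0 h, and at 8 h their signal was at least 1.28-fold and 1.19-fold lower.

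Most lists fixed beforehand could not be described. Of 23 lists, which include p53 targets, damage-response long noncoding RNAs, histones, cell-cycle genes and double-strand-break repair, 18 had no member with a named probe and 4 had 1 to 4. The probe of lincRNA-p21, a p53-induced noncoding RNA, was not well above background on any array. That of TncRNA (NEAT1), which builds the paraspeckles of the nucleus, was well above background at all 3 times but carried an outlier flag on each array. With such spots kept, a value looked up after the others, it differed by 0.43 at 4 h and 0.48 at 8 h, less than 2-fold. CDKN1A, MDM2, CDKN2B-AS1, MALAT1, GAS5, ATM, E2F1 and PHF17 had no named probe.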

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

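These results stood out by a rule that compares both treated times or by a signal outside the main measurement, and no explanation was tested for them. Among named probes detected on all 3 arrays, 5 lay on opposite sides of the untreated array at 4 h and 8 h and were 2-fold or more apart between these times. With 1 array per time, this difference was not tested. The probe named mascRNA, a small RNA processed from the end of the MALAT1 transcript, differed from 0 h by 1.20 ± 0.23 (log2) at 4 h and by -0.33 ± 0.29 at 8 h. The corresponding values were 0.75 ± 0.21 and -0.67 ± 0.23 for uc.63-, -0.087 ± 0.20 and 0.97 ± 0.20 for the HOXC6 exon 1 probe, -0.88 ± 0.25 and 0.23 ± 0.23 for nc-HOXB9-195, and -0.029 ± 0.22 and 1.18 ± 0.22 for nc-HOXB1-156. The 4 h values of the HOXC6 and nc-HOXB1-156 probes were within their error of 0. After normexp, nc-HOXB1-156 lay at 0.0038 at 4 h, on the same side as at 8 h, and between the times it differed by 0.88 and nc-HOXB9-195 by 0.74, under 2-fold. Over all 8824 probes, 6 changed 2-fold or more in opposite ways, against 10.1 in the simulation of unchanged arrays. The simulated noise holds any real change from 4 h to 8 h, so 10.1 may be too high.

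Some control spots, for which the labels name no added spike-in RNA, gave signal on the 8 h array. Of the ERCC spike-in spots, 2 were well above background at 8 h, with a highest signal of 129, against 54.8 at 0 h. Of the 36 DCP control spots, 2 were well above background at 8 h, with a highest signal of 144, against 33.0 at 0 h. The highest unmarked spot named as a negative control had a signal of 65.6 at 8 h.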

How the results depend on the processing

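With 1 array per time, no result has a replicate check, and signal over background limits most of the array, since only 16509 of 60639 probes were well above background on at least 1 array. No paired analysis was possible because each group holds 1 array. Choices made after seeing the data were the signal before detrending, which moved no count by over 1.5 times, and counting within the probes of the authors' table. Counts follow as higher and lower at 4 h, at 8 h, from 4 h to 8 h and at both times, against the main 737 and 558, 1218 and 729, 1114 and 403, and 463 and 193. Normexp gave 409 and 255, 792 and 464, 502 and 226, and 231 and 123. The authors' value table, with fewer probes, gave 260 and 180, 336 and 440, 271 and 335, and 130 and 76. Its probes with the scanner signals gave 316 and 177, 441 and 308, 403 and 212, and 174 and 70. Bright probes alone gave 331 and 167, 499 and 360, 264 and 200, and 222 and 83. Without a filter on detection they were 4373 and 3930, 6793 and 3259, 5761 and 2088, and 2574 and 1885, and at 3-fold 216 and 111, 513 and 165, 309 and 50, and 129 and 34. Scaling on all probes gave 652 and 1918 at 8 h, 567 and 1016 from 4 h to 8 h, and 287 and 391 at both times. Quantile normalization gave 678 lower from 4 h to 8 h, and keeping marked spots 290 lower at both times.

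The share of noncoding probes changed 2-fold (9.41% at 4 h, 20.8% at 8 h) was 5.88% and 9.09% at 3-fold, and 9.76% at 8 h without a filter. That of coding probes (13.8% and 27.3%) was 0% and 9.09% at 3-fold, and at 4 h 6.90% after normexp, 8.33% with marked spots kept and 8.99% without a filter. The noncoding median (-0.03 at 4 h, -0.14 at 8 h) became -0.14 and -0.57 with scaling on all probes and -0.17 and 0.27 without a filter, and at 8 h -0.26 with median centring and -0.27 in the authors' table. The coding median (-0.01 and -0.43) became -0.13 and -0.85 on all probes, -0.13 and 0.021 without a filter, and -0.16 at 8 h after cyclic loess. The HOX median at 8 h (-0.43) became -0.86 on all probes and -0.0699 without a filter. For other settings these values moved by less than the SD of random lists, and apart from fewer probes or a stricter threshold the cause was not tested. Of the 22 changes of the 15 probes that the naming rule took for the size of their change, without the list members HOXA5 and HOXB8, 21 were still 2-fold the same way after quantile normalization, 21 after cyclic loess and 20 with scaling on all probes. Since the rule asked most of them to pass normexp, that setting does not test them.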

Other observations

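Tests chosen only after the result was seen were those of the untreated array for the HOX genes, of spot artifacts, and of the scaling level, dim probes and detrending for the split of changed probes.

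Several ultraconserved probes were seen on 1 array of a pair. At 8 h, uc.238- was at least 5.99-fold higher, uc.414- at least 5.40-fold and uc.462- at least 3.56-fold. In untreated cells alone, uc.188+, the other strand of uc.188-, was well above background, at least 3.63-fold lower at 8 h, as were uc.390+ and uc.296-, at least 2.69-fold and 2.65-fold lower. In the HOXB cluster, nc-HOXB4-176 was at least 5.58-fold higher at 8 h than at 0 h. These probes were picked after their values were seen.

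The lower signal of HOX coding genes at 8 h was weighed against technical explanations. The random lists were matched on signal, so scaling that depends on brightness alone would move them and the HOX genes alike. The percentile of 1.10 after cyclic loess is therefore no separate test of such scaling. The median of the 21 genes itself was -0.35 after cyclic loess, against -0.43 under the main scaling. Detrending on the 0 h and 8 h arrays is argued against, with percentile 0.54 before that step. An untreated array with high HOX signal is argued against by the 8 h minus 4 h difference, which leaves it out, at percentile 0.01. A difference of the 8 h culture or array for another reason than the drug cannot be told apart from a response to it. There was 1 array at 8 h and no untreated array at that time, so time in culture stays open too. HOX genes are also not independent of each other.

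Ultraconserved probes seen on 1 array only could be spot artifacts. Of 953 ultraconserved probes, 14 (1.47%, exact 95% interval 0.81 to 2.45%) were well above background on only 1 of the 0 h and 8 h arrays with a bound of 2-fold or more. Of 1621 control spots without a target, 3 did so (0.185%, 0.04 to 0.54%). This argues against spot artifacts unrelated to probe sequence for the set at 8 h. The control spots include repeated ones, such as those of the 3xSLv1 hairpin (308 spots on the array), which the interval counts as independent. Artifacts tied to the sequence of a probe were not tested. For 4 h the counts were 7 of 952 (0.30 to 1.51%) and 0 of 1607 (0 to 0.23%), with intervals that did not overlap. Among these control spots, 0 of the 553 named as negative controls did so (0 to 0.66%), an interval that overlaps that of the ultraconserved probes. Artifacts stay open at 4 h, since the answer depends on the controls taken. At both times any single probe stays open, as does a difference between cultures with or without a link to the drug.

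The excess of higher over lower probes at 8 h, 62.6% of changed probes, may come from the level to which each array is scaled, since it became 52.0% with median centring, which changes the level alone, and 46.5% after quantile normalization, which also changes the shape. As the whole cause, a dependence on brightness is argued against by 61.1% after cyclic loess, an offset of dim probes by 58.1% among probes at or above the median signal, and detrending by 62.0% before that step. The lowest normalized log2 signal of a detected probe was -3.67 at 8 h and -3.98 at 0 h, so dim probes that fell could be left out. In the dimmest eighth, 93 were higher and 14 lower. Whether more transcripts rose than fell stays open.

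A hypothesis was that probes with consecutive identifiers change alike, as they would if identifiers follow transcripts or loci. Across 1602 pairs the correlation of the 8 h differences was 0.21, against -0.05 to 0.05 (central 95%) for signal-matched partners. Among these pairs, 60 changed 2-fold in the same way and 17 in opposite ways, and 56.3% had the same sign. At 4 h the correlation was 0.12 over 1638 pairs (random -0.05 to 0.04), with 31 pairs in the same way, 17 in opposite ways and 51.5% of the same sign, so any relation is weak. The spots of such pairs lay a median of 134.4 spot positions apart, within the 130.3 to 140.3 of random pairs. This argues against closeness on the slide for the pairs as a whole. A median cannot show whether a minority of pairs lies close, and what such pairs add to the correlation was not tested. Shared or overlapping target sequence stays a candidate explanation and was not tested.

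A second hypothesis was that noncoding and coding probes named for 1 HOX gene change alike. Across 13 genes, each with its brightest noncoding probe, the correlation of the 8 h differences was -0.32, within the -0.55 to 0.55 of random pairings. HOXD8 and HOXD4 exons were at -1.95 and -1.86 while the brightest noncoding probes named for them were at 0.77 and 0.84. Other noncoding probes named for them went with the exons, nc-HOXD8-20 at -1.59 and nc-HOXD4-22 at -1.43, so the relation depends on the probe taken. For the strands of ultraconserved elements, 1 pair was measured at 0 h and 8 h, uc.472, with -1.46 on the plus and -1.20 on the minus strand, too few to test.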
